A study of Mus musculus with 6 samples.

How the data were processed

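RNA of isolated pancreatic islets was measured on 6 Affymetrix mouse arrays, 3 from control mice and 3 from mice in which Vhlh was deleted in beta cells by Cre recombinase expressed from the rat insulin promoter. Per the labels, small amounts of total RNA were amplified by consecutive rounds of cDNA synthesis and in vitro transcription before hybridization. Per the labels, arrays 01, 02 and 03 of each genotype came from mice of 26, 20 and 18 weeks, recorded as male, female and male. The design text says that each genotype gave 3 batches of islets, so the p-values measure the spread between these batches, and the number of mice behind a batch was not given in the sources used here.

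The deposited values are the authors' MAS5 signal intensity per probe set on a linear scale, made with GCOS 1.4 and MAS5 per the submitters' processing notes. Checked on the values, the 2% trimmed mean was 500.003 on every array, so each array carries the authors' global scaling. No further normalization between arrays was recorded in the labels. No detection call, scanner file, scan date or slide was used here. Array medians lay between 101.9 and 122.7 signal units, and no signal was at or below 0. The number of arrays limits the precision of every value.

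The table held 45101 probe sets, of which 64 controls were left out. Of the remaining 45037, the platform annotation gave 34945 exactly 1 gene symbol, 932 several and 9160 none. Symbols were updated through Entrez identifiers in a RefSeq gene table of assembly GRCm38.p6, which matched 34741 probe sets and changed 0 symbols. That table was used for names alone, and no coordinates are given. A gene was represented by its probe set of highest mean log2 signal, leaving out probe sets whose name ends in _x_at unless the gene had no other. That gave 18193 genes. A gene was tested if its signal was above the array's median on at least 3 of the 6 arrays, which left 11609 genes, 38 of them represented by a probe set of the _x_at kind, which can bind related transcripts.

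The log2 signals were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with an intensity trend, with statmod 1.5.0) and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. No value was added before taking log2. Fold changes are ratios of geometric means, knockout over control, and errors of log2 differences are limma's moderated standard errors. Adjusted p-values below come from limma unless another test is named. For the Vhl probe sets, a two-sided exact permutation test of the 6 log2 values was added, whose smallest possible p is 0.1.

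The 24 gene lists, the design and most alternatives were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 23 lists with at least 2 tested genes. The erythroid list had 1 tested gene and was not tested. Camera with an estimated correlation and fry, limma's rotation test of whether a list's genes move one way on balance, were alternatives. For members of a list, adjusted p-values are also given "adjusted over the list alone". Pairs of lists that share genes are HIF glycolysis and genes kept low in beta cells (Hk1 and Ldha), other HIF genes and angiogenic factors (Adm), angiogenic factors and genes kept low in beta cells (Cxcl12), genes kept low in beta cells and oxidative stress defence (Cat), progenitor and duct genes (Sox9), and unfolded protein response and immediate-early genes (Atf3).

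The rule for named genes, fixed beforehand, took 16 genes chosen for the design, the up to 10 largest rises and falls that passed the threshold with no overlap between groups (the 3 of lowest p where none passed), and the up to 4 members of lowest p of each list that passed or that concerned HIF, beta cells, secretion, the tricarboxylic acid cycle or oxidative phosphorylation. Of the 16 genes, 3 had no probe set with a single symbol in the annotation used here and were not analysed. Genes named outside the rule were chosen after their values were seen, as is said where they appear. Sex-linked transcripts were read as a check of the labels. Of 31 named genes with more than 1 probe set bright enough to test, 26 had probe sets that all moved one way; Arnt, Egfl7, Hif1a, Pdgfb and Stx1a did not.

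Both genotypes carry the numbers 01, 02 and 03, with the same age and recorded sex at each number. Deviations from the group means over the 11609 genes correlated within each same-numbered pair, at 0.15 for number 01, 0.42 for number 02 and 0.43 for number 03. By the rule that every such correlation exceeds 0.1, the numbers pair the samples. Control 01 with knockout 02 also reached 0.14, so the rule hardly tells the pair numbered 01 from a pair of unlike numbers. The other correlations between unlike numbers were below 0. Deviations from a group mean sum to 0 within each genotype, so these negative values largely follow from the positive ones and add no support. Values with the replicate block are given beside a result where they change its call or move a count by over 1.5 times.

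Signs of RNA quality differed between arrays. The ratio of the actin control's 3' to 5' signal was 3.83, 3.34 and 15.1 on control arrays 01 to 03 and 11.3, 3.43 and 7.97 on knockout arrays 01 to 03. The corresponding Gapdh ratios were 5.71, 4.78 and 5.74 in controls and 11.9, 6.12 and 4.64 in knockouts. Correlations of log2 signals between arrays ranged from 0.877 to 0.948 within a genotype and from 0.865 to 0.949 between genotypes.

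Alternatives were quantile normalization, centring on array medians, no filter or a filter at the 70th percentile, a pseudocount of 25.3 signal units (the 20th percentile of all signals), the mean of a gene's probe sets, every probe set on its own, eBayes without trend or with robust fitting, array weights, a replicate block, recorded sex as a covariate, an adjusted p under 0.10 and leaving out each array in turn. An alternative without both arrays numbered 03, one with the acinar marker mean as a covariate and one with the actin ratio as a covariate were added after seeing the data. The procedure was tested on 5 simulated tables built from the real means and spreads of the probe sets, each with 200 genes changed by known folds. Of the genes changed 2-fold, 4-fold and 8-fold, 3.88%, 38.2% and 61.2% were called, and the median estimates were 0.98, 2.02 and 3.01 on the log2 scale. There were 8 false calls in all. A list raised by 0.6 on the log2 scale was found in 5 of the 5 tables, and 0 of 111 tests of other lists passed. These simulated arrays had no shared variation between genes.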

Results

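Gene expression was measured in isolated pancreatic islets of 3 control and 3 Vhlh knockout samples, 1 array each. Islets are the endocrine clusters of the pancreas and consist mainly of insulin-secreting beta cells, with alpha, delta and PP cells, vessels and stroma. Vhlh, named Vhl in the annotation, encodes the von Hippel-Lindau protein, which marks hypoxia-inducible factor (HIF) subunits for degradation when oxygen is present. The comparison of the 2 genotypes asks which transcripts differ in islets whose beta cells lack this protein. Knockout and control arrays had the same scaling, and the median log2 difference over the 11609 genes tested was -0.00028.

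Vhl itself was lower in the knockout samples by a margin that did not pass the threshold. Its brighter probe set had a mean log2 signal of 9.29 ± 0.44 (SD, n = 3) in controls and 8.59 ± 0.24 (SD, n = 3) in knockouts, so the knockout level was 61.7% of the control level. The log2 difference was -0.70 with a standard error of 0.32 and an adjusted p of 0.9998. It was lower in the knockout in 3 of the 3 same-numbered pairs, and the two-sided exact permutation p was 0.2 where the smallest possible is 0.1. The other probe set was too dim to test, with a level of 70.6% of control and an exact permutation p of 0.6. Where these probes lie relative to the deleted part of the gene was not analysed here, and islets also hold cells in which the gene is intact, so this value is a weak check of the labels.

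The single-gene differences of lowest p were rises of Ak4, a mitochondrial adenylate kinase, and Prelid2, a member of the PRELI domain family. Ak4 was 79.1-fold higher in knockout samples, a log2 difference of 6.31 with a standard error of 0.55 and an adjusted p of 0.0103. Its knockout signals were 2471, 1763 and 2471 against 18.1, 72.1 and 16.7 in controls. The control signals lay below the array medians, so the size of the fold rests on dim values: with a pseudocount the log2 difference was 5.31, and a second bright Ak4 probe set rose by 3.31. Prelid2 was 7.90-fold higher, with a log2 difference of 2.98, a standard error of 0.28 and an adjusted p of 0.0107. Both genes had 3 of 3 knockout signals above all control signals.

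These were the 2 genes of 11609 that passed, both rises, and 5 had an adjusted p under 0.10, the other 3 being Egln3, Ldha and Pfkp. With the replicate block 6 genes passed, all rises: Ak4, Prelid2, Ldha, Pgk1, Pfkl and Tpi1, the last pair chosen after their values were seen. In that fit 10 genes had an adjusted p under 0.10. At an unadjusted p under 0.05 there were 300 genes, 231 higher and 69 lower in the knockout, where 580.45 would be expected by chance. With the block there were 584, 425 higher and 159 lower. The 3 lower genes of smallest p did not pass: Exosc1, an exosome subunit, differed by -1.52 (adjusted p 0.607), C920006O11Rik by -3.50 (adjusted p 0.870) and Cib3 by -1.89 (adjusted p 0.9998). With the mean of a gene's probe sets Exosc1 was at -0.76 and C920006O11Rik at -1.91. Knockout and control signals did not overlap for 462 genes with higher and 322 with lower knockout values, together 6.75% of genes where chance gives 10%. The count was 0 without knockout 01 and 0 without knockout 03 (498 and 254 genes at an unadjusted limma p under 0.05), 1 without control 01 (Ak4, with Prelid2 at an adjusted p of 0.109) and 5 without control 02. The folds stayed about as large where leaving out an array lost the calls. The log2 difference of Ak4 was 6.22 without knockout 01 and 6.22 without knockout 03, and that of Prelid2 was 2.89, 2.97 and, without control 01, 2.84. With the mean of a gene's probe sets the log2 differences fell to 2.06 for Ak4 (adjusted p 0.875) and 2.08 for Prelid2 (adjusted p 0.496). Neither passed there, and Adm and Pgk1 did.

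**Figure D1:**
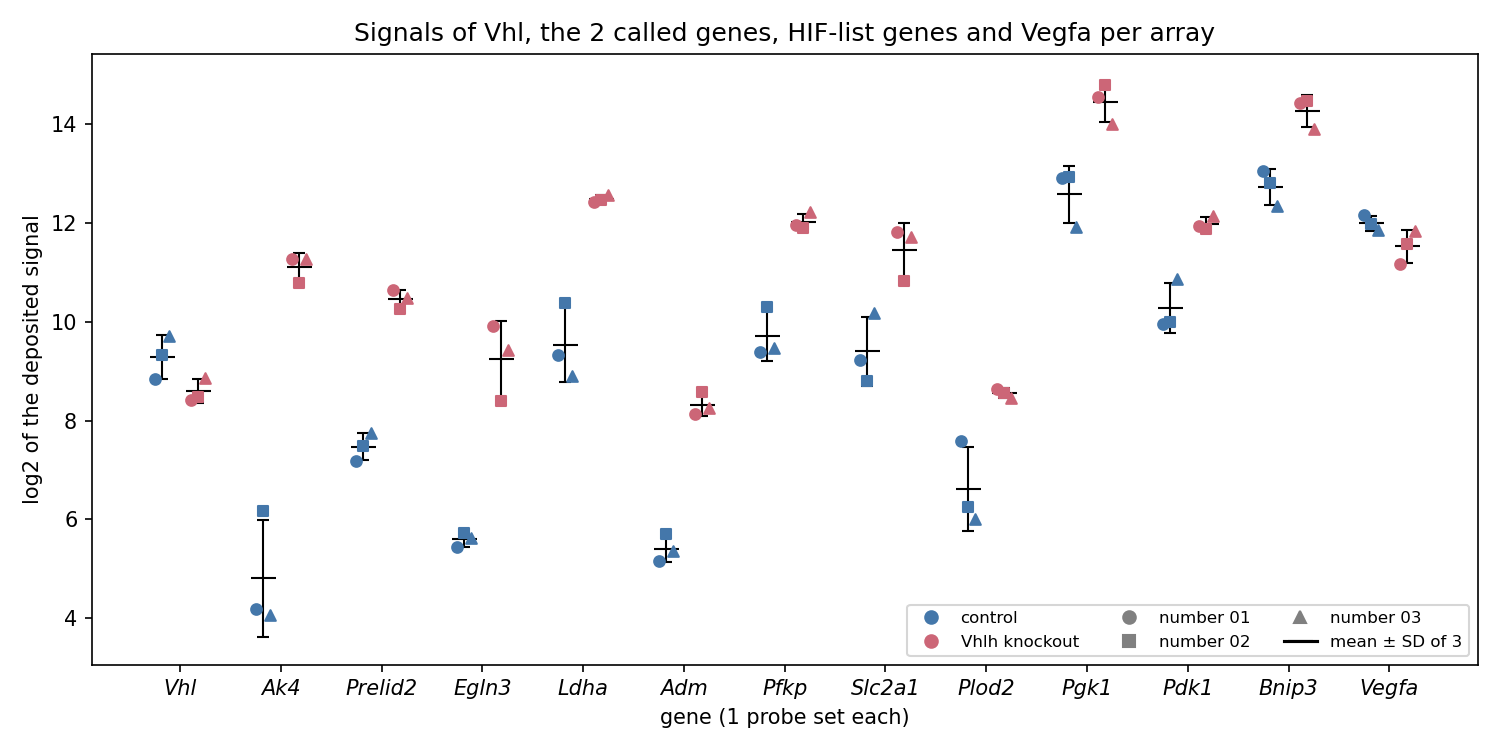
Log2 of the deposited signal (vertical axis) of 13 genes (horizontal axis) on each of the 6 arrays, control in blue and Vhlh knockout in red, with symbols for the array number and black bars for the mean ± SD of 3 arrays. The knockout values of Ak4, Prelid2 and the HIF-list genes lie above all control values, those of Vegfa lie below all control values, and those of Vhl overlap the control values.

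Glycolytic genes induced by HIF rose together in the knockout islets. Of the 21 genes fixed for this list 17 were tested, all 17 had a positive log2 difference, and 11 passed when adjusted over the list alone, against 0 when adjusted over all genes. Ldha, the lactate dehydrogenase subunit that favours lactate formation, was 7.70-fold higher (9.54 ± 0.75 in controls and 12.48 ± 0.08 in knockouts, mean log2 ± SD, n = 3 each). Pfkp, a phosphofructokinase, was 4.96-fold higher with a log2 difference of 2.31 (SE 0.31), Slc2a1, a glucose transporter, was 4.16-fold higher with 2.06 (SE 0.41), Pgk1, phosphoglycerate kinase, was 3.66-fold higher with 1.87 (SE 0.34), and Pdk1, a kinase that inhibits pyruvate dehydrogenase, was 3.28-fold higher with 1.71 (SE 0.31). Over all genes their adjusted p-values were 0.0606 for Ldha, 0.0863 for Pfkp, 0.487 for Slc2a1 and 0.282 for Pgk1 and Pdk1; with the replicate block Ldha (0.0476) and Pgk1 (0.0432) passed. With the mean of a gene's probe sets the Pfkp difference was 0.65. The list's mean log2 difference was 1.37, with adjusted camera p 5.4e-28, and the call held with an estimated correlation (adjusted p = 0.0220) and with fry (adjusted p = 0.0212). The mean was 1.44, 1.24 and 1.42 in the pairs numbered 01, 02 and 03.

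Other genes induced by HIF rose as well. All 24 tested members of this list had a positive log2 difference, with a mean of 0.97, and the list passed with adjusted camera p 5.5e-19, with an estimated correlation (adjusted p = 0.0465) and with fry (adjusted p = 0.0229). Adjusted over the list alone, 6 members passed without and 11 with the replicate block, and 0 passed over all genes. Egln3, a prolyl hydroxylase that acts on HIF, was 12.6-fold higher (log2 difference 3.66, SE 0.46, adjusted p 0.0606 over all genes), and its second bright probe set differed by 3.61. Adm, which encodes the vasodilator adrenomedullin, was 7.56-fold higher (2.92, SE 0.45), Plod2, a collagen lysyl hydroxylase, 3.84-fold (1.94, SE 0.47), and Bnip3, a mitophagy receptor, 2.92-fold (1.54, SE 0.27). Control signals of Egln3 and Adm were at most 52.9 and 51.9, below the array medians, so their folds rest on dim values, and a second Adm probe set differed by 4.41. For Adm, Plod2 and Bnip3 the adjusted p over all genes was 0.166, 0.870 and 0.282.

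The transcripts of the HIF subunits themselves did not pass the threshold. Epas1, which encodes HIF-2 alpha, differed by 0.69 (SE 0.29), Hif1a by -0.44 (SE 0.34) and Arnt by -0.17 (SE 0.34), each with adjusted p 0.9998. Epas1 was at 0.45 without knockout 03 and at 0.27 with the mean of its probe sets. The bright probe sets of Hif1a and of Arnt disagreed in direction, and the Hif1a difference was 0.03 with the mean of its probe sets.

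Vegfa, which encodes the main growth factor of vessels, did not go with the HIF lists. Its log2 difference was -0.46 with a standard error of 0.27 and a 95% interval from -1.07 to 0.14, and its signals of 2312, 3072 and 3651 in knockouts lay below those of 4569, 4030 and 3699 in controls (adjusted p 0.9998). Without knockout 01 the difference was -0.29. The list of angiogenic factors was higher, with 11 tested genes, a mean log2 difference of 0.53 and an adjusted camera p of 0.0191 (adjusted p = 0.220 with an estimated correlation). Adm was its 1 member that passed when adjusted over the list alone, and 4 of the 11 members had a negative difference. The list lost its call without control 03 (adjusted p 0.222), knockout 02 (0.0885) or knockout 03 (0.0866), and with array weights (0.115). It also lost it without both arrays numbered 03 (mean 0.35, adjusted p 0.297). With the stricter filter on dim probe sets its mean turned to -0.013 (adjusted p 0.734).

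Markers of endothelial cells were higher in the knockout islets. All 16 tested members had a positive difference, with a mean of 0.54 and an adjusted camera p of 3.1e-06 (adjusted p = 0.121 with an estimated correlation), but 0 members passed when adjusted over the list alone. The vascular growth factor receptors Kdr (0.64, SE 0.26) and Flt1 (0.66, SE 0.36), the apelin receptor Aplnr (1.85, SE 0.69) and Egfl7 (0.61, SE 0.28) had the lowest p. Aplnr was at 1.03 without knockout 03 and Flt1 at 0.40 without control 02. One of the Egfl7 probe sets went the other way. The list's mean above controls was 0.37 on knockout 01, 0.36 on knockout 02 and 0.90 on knockout 03.

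Genes of insulin and beta-cell identity were lower as a group by a small margin. The mean log2 difference of the 20 tested genes was -0.20 with an adjusted camera p of 0.00787 (adjusted p = 0.220 with an estimated correlation). Of these genes 13 were below and 7 above 0, and 0 passed when adjusted over the list alone. The members of lowest p were Ucn3, a peptide of mature beta cells (-0.90, SE 0.41), Glp1r, the incretin receptor (-0.83, SE 0.39), the cation channel Trpm5 (-0.84, SE 0.43) and the transcription factor Neurod1 (-0.41, SE 0.22). Ins2, an insulin gene, differed by 0.39 (SE 0.36) through a probe set of the _x_at kind, the transcription factor Pdx1 by -0.20 (SE 0.28) and the glucose transporter Slc2a2 by -0.35 (SE 0.26). Without control 01 Ucn3 was at -0.55, Trpm5 at -0.52 and Slc2a2 at -0.16, without control 02 Trpm5 was at -1.27, and without knockout 02 Pdx1 was at -0.07. Ins2 ranged from 0.13 without knockout 01 to 0.85 without knockout 03. The list's call was also lost without control 01 (0.106), knockout 02 (0.0703) or knockout 03 (0.249). Its mean was lower in the knockout in 3 of the 3 pairs, by values between -0.25 and -0.18. The call was also lost with the acinar marker mean as a covariate (adjusted p 0.0721). Markers of other cell types, given below, were higher in the same pairs, apart from acinar markers in the pair numbered 03. Whether the composition of the samples differed between genotypes is not decided by these lists, so the lower beta-cell list was not separated from such a difference.

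Genes that beta cells normally keep low were higher. All 17 tested members had a positive difference, with a mean of 0.94 and an adjusted camera p of 2.3e-16 (adjusted p = 0.166 with an estimated correlation). Adjusted over the list alone 4 passed, and 5 with the replicate block. The 4 were Ldha, Ndrg2 (3.89-fold, log2 difference 1.96, SE 0.30), the hydrogen peroxide-degrading enzyme catalase, Cat (1.89-fold), and the growth factor-binding protein Igfbp4 (2.41-fold). The log2 difference of Igfbp4 was 1.27, and 0.55 with the mean of its probe sets. Ldha is also a HIF target. The list's mean differed by 0.61, 0.65 and 1.55 in the pairs numbered 01 to 03, and the matrix and neural marker lists below were likewise highest in the pair numbered 03, at 1.76 and 1.45. Genes kept low in beta cells can be expressed in the other cells of islets, and whole islets do not show which cells the signal came from. The list of endocrine progenitor and dedifferentiation genes, with 6 tested members, had a mean of 0.69 and did not pass (adjusted p 0.199; 0 members adjusted over the list alone, 1 with the replicate block), nor did genes of stimulus-secretion coupling, with a mean of -0.11 over 23 genes (adjusted p 0.185). The progenitor list passed without control 02 (0.73, adjusted p 0.0471). The secretion list passed as lower without knockout 01 (-0.21, adjusted p 0.0124), without control 02 (-0.18, adjusted p 0.0471) and with the mean of a gene's probe sets (-0.19, adjusted p 0.0314), and its mean was -0.025 without knockout 03. Kcnj11, a subunit of the potassium channel that couples metabolism to secretion, differed by -0.41 (SE 0.37), and by -0.17 without control 01 and -0.73 without control 03.

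**Figure D2:**
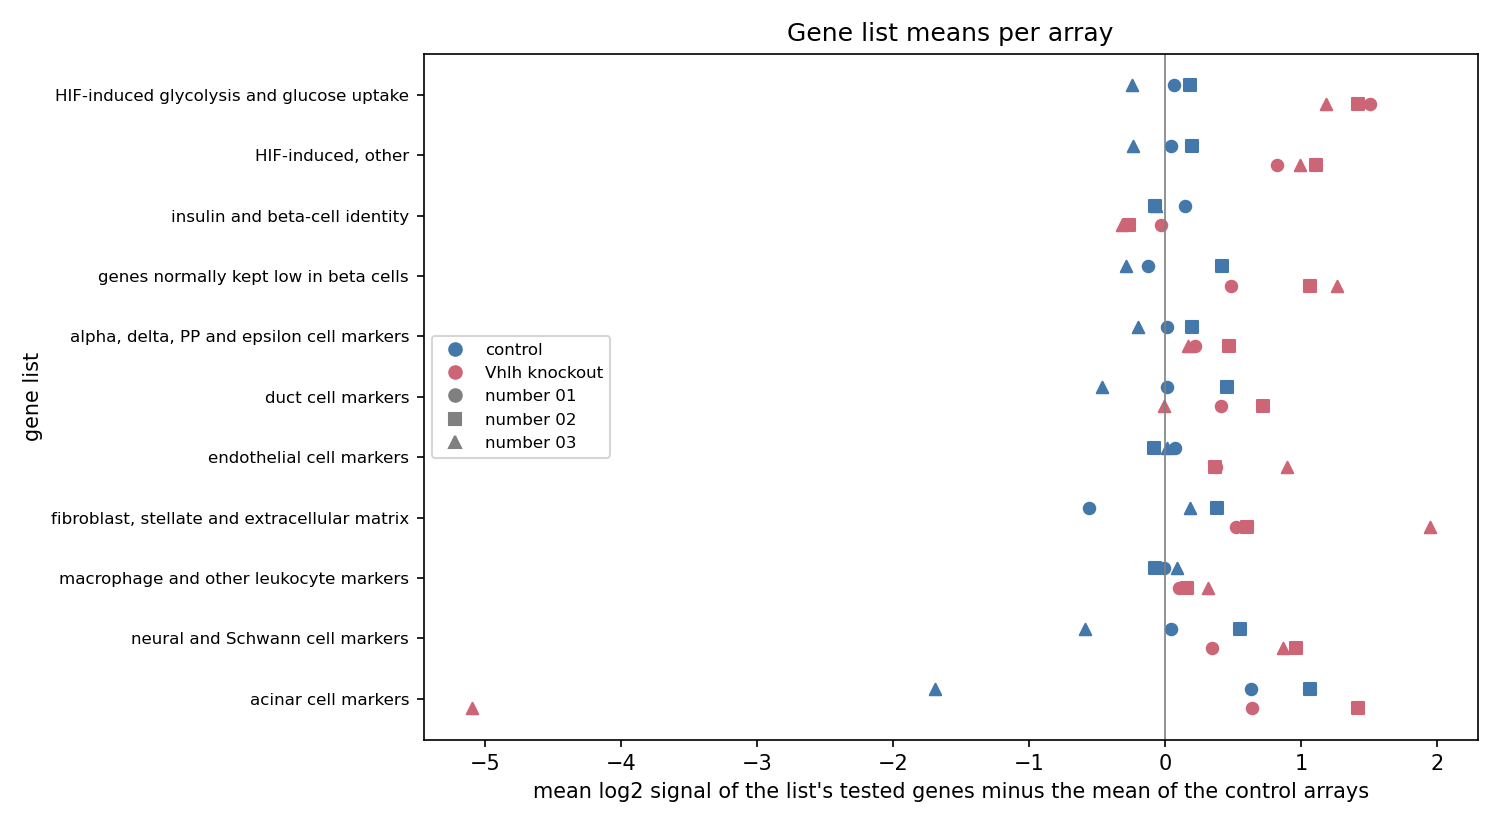
Mean log2 signal of the tested genes of 11 lists on each array (horizontal axis) minus the mean of the 3 control arrays, with control in blue, Vhlh knockout in red and symbols for the array number. Both HIF lists separate the genotypes, as do the endothelial, matrix, leukocyte and kept-low lists by smaller margins. The acinar markers reach -5.10 on knockout 03 and -1.69 on control 03.

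Markers of the other cells found in islet preparations differed in size and evenness. Alpha, delta, PP and epsilon cell markers were higher, with 10 of 10 tested genes above 0, a mean of 0.28 and an adjusted camera p of 0.00611 (adjusted p = 0.220 with an estimated correlation), and 0 members passed when adjusted over the list alone. Among them the somatostatin gene Sst differed by 0.34 (SE 0.22), Rbp4 by 0.35 (SE 0.24), Hhex by 0.76 (SE 0.37) and Irx1 by 0.49 (SE 0.30), while Gcg, the glucagon gene, differed by 0.09 (SE 0.24), a value that turned to -0.01 with quantile normalization. Gcg signals were near the top of the arrays' range, for example 55684 on knockout 02 and 31892 on knockout 03 with array maxima of 76826 and 40917. A change of Gcg could thus be compressed, which was not tested. Sst was at 0.20 without knockout 01, Rbp4 at 0.21 without knockout 03 and Hhex at 0.33 without both arrays numbered 03. That list lost its call without control 03 (mean 0.18, adjusted p 0.168) or knockout 02 (0.19, adjusted p 0.174), with no filter on dim probe sets (0.19, adjusted p 0.0715) and with every probe set on its own (0.13, adjusted p 0.0655). Duct markers (mean 0.37 over 12 genes, adjusted p 0.0998) and leukocyte markers (mean 0.19 over 15 genes, adjusted p 0.156) did not pass. Duct markers passed without knockout 03 (0.56, adjusted p 0.00562), without control 02 (0.60, adjusted p 0.00961), with every probe set on its own (0.28, adjusted p 0.0412), with the acinar covariate (0.50, adjusted p 0.00943) and with the actin covariate (0.44, adjusted p 0.0364), and their mean was 0.14 without control 03. Leukocyte markers passed with every probe set on its own (0.14, adjusted p 0.0429). Neural and Schwann cell markers were higher, with a mean of 0.72 over 9 genes and an adjusted p of 0.00701 (adjusted p = 0.220 with an estimated correlation), led by the neurofilament gene Nefl (1.96, SE 0.84) and Prph (1.68, SE 0.73), of which neither passed. Without control 03 Nefl was at 0.99 and Prph at 0.81. The neural call was lost without control 03 (mean 0.43, adjusted p 0.120), without knockout 02 (0.60, adjusted p 0.0699) and without both arrays numbered 03 (0.36, adjusted p 0.206).

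Fibroblast, stellate and extracellular matrix genes were higher, most of all on knockout 03. The mean log2 difference of the 19 tested genes was 1.02 with an adjusted camera p of 6.3e-12 (adjusted p = 0.220 with an estimated correlation). Fn1, which encodes fibronectin, was the 1 member that passed when adjusted over the list alone (2.60-fold, log2 difference 1.38, SE 0.33, adjusted p 0.0427), and with the replicate block it did not (adjusted p 0.0519). The collagen genes Col6a2 (2.22, SE 0.84) and Col6a1 (0.84, SE 0.35) and the pericyte receptor Pdgfrb (1.22, SE 0.52) did not, and without knockout 03 Col6a2 was at 1.46 and Col6a1 at 0.54. The list's mean above controls was 0.52, 0.60 and 1.94 on knockouts 01 to 03, and without knockout 03 the difference was 0.56.

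Acinar cell markers, which stand for exocrine tissue left on the islets, differed between arrays far more than between genotypes. The mean log2 difference of the 19 tested genes was -1.01, with an adjusted camera p of 0.00447 (adjusted p = 0.531 with an estimated correlation). The list's mean relative to controls was 0.64, 1.42 and -5.10 on knockouts 01 to 03 and 0.63, 1.06 and -1.69 on controls 01 to 03. Cela3b, an elastase gene, had signals of 40510, 43891 and 513 in knockouts and 31939, 35788 and 11584 in controls, and Rnase1 had 25327, 55909 and 555 against 31844, 39463 and 6697. Without knockout 03 the list passed the other way, as higher, with a mean of 1.03 and an adjusted camera p of 7.2e-09. It also passed as higher without both arrays numbered 03 (0.18, adjusted camera p 1.1e-04). The camera call of this list thus turned with the arrays used. Its call was lost without control 01 (adjusted p 0.0555) or control 02 (0.189). Knockout 03, the array with the lowest acinar signal, was also the one with the highest matrix and endothelial marker means.

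Stress and inflammation genes were higher as groups, most in the pair numbered 03. Immediate-early and dissociation stress genes, which islet isolation itself can induce, had a mean difference of 0.61 over 15 genes and an adjusted camera p of 1.1e-05 (adjusted p = 0.310 with an estimated correlation), at 0.34, 0.39 and 1.08 in the pairs numbered 01 to 03. Klf6 (1.12, SE 0.38), Ier3 (1.11, SE 0.43) and Atf3 (1.25, SE 0.56) were among its members of lowest p, and 0 passed when adjusted over the list alone, against 3 with the replicate block. Without knockout 03 the list's mean was 0.39 and Atf3 was at 0.82. Inflammatory and interferon response genes had a mean of 0.39 over 10 genes and an adjusted p of 0.0285 (adjusted p = 0.446 with an estimated correlation), with the chemokine gene Cxcl1 at 1.04 (SE 0.63) and pair means of 0.11, 0.25 and 0.81. Without knockout 03 Cxcl1 was at 0.37, and without both arrays numbered 03 at 0.18. The list's call was lost without control 01 (mean 0.25, adjusted p 0.304), knockout 02 (0.40, adjusted p 0.105) or knockout 03 (0.10, adjusted p 0.672). It was also lost without both arrays numbered 03 (0.18, adjusted p 0.270), with no filter on dim probe sets (0.42, adjusted p 0.0844) and with the acinar covariate (0.27, adjusted p 0.185).

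Lists of mitochondrial and other metabolism did not pass. The tricarboxylic acid cycle genes had a mean log2 difference of -0.05 over 23 genes (adjusted p 0.485) and the subunits of oxidative phosphorylation 0.06 over 42 genes (adjusted p 0.434), with 0 members of either passing when adjusted over the list alone. Genes of mitochondrial biogenesis and dynamics had a mean of -0.08 (adjusted p 0.425), the unfolded protein response 0.10 (adjusted p 0.520), oxidative stress defence 0.16 (adjusted p 0.108) and the cell cycle 0.33 (adjusted p 0.104, and 0.0195 with the replicate block). The cell cycle list also passed without control 03 (0.53, adjusted p 0.0137), with array weights (0.48, adjusted p 0.0200) and with every probe set on its own (0.24, adjusted p 0.0394), and oxidative stress defence passed without control 02 (0.27, adjusted p 0.0256) and with the stricter filter (0.17, adjusted p 0.0416). Fatty acid oxidation and lipid metabolism had a mean of 0.09 and a median of -0.01 (adjusted p 0.601). In that list Scd1, a fatty acid desaturase chosen after its value was seen, was 3.10-fold higher and passed when adjusted over the list alone (adjusted p 0.0379). In all, 12 of the 23 lists passed, 10 higher and 2 lower in the knockout; 2 passed with an estimated correlation and 2 with fry, the HIF lists in both cases, 13 passed with the replicate block, and 7 passed without knockout 02.

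Sex-linked transcripts went against the labels on both arrays numbered 03. These are recorded as male in both genotypes, yet Xist, which is transcribed from the inactive X chromosome of females, had signals of 16381 on control 03 and 13694 on knockout 03. The arrays recorded as female had 11319 and 13783, and the other arrays recorded as male 163 and 187. The sexes read this way are the same in both genotypes at each number, so genotype and sex are not confounded.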

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

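The tests in this part were chosen after the result was seen. Xist appeared on 2 arrays recorded as male, with a signal of 16381 on control 03 and 13694 on knockout 03, above the 163 and 187 of the male arrays numbered 01. Y-linked Eif2s3y, chosen after its values were seen because the Y-linked gene of the fixed rule was not analysed here, had signals of 2.77 and 21.5 on those 2 arrays, 9.92 and 12.3 on the arrays recorded as female and 1646 and 1801 on the male arrays numbered 01. Xist was among the genes tested between genotypes, where it differed by 0.08 (adjusted p 0.9998); its pattern over the recorded sexes belongs to no comparison of the report.

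A swap with the arrays recorded as female argues for Y-linked signal on those, and 0 of the 2 had Eif2s3y above the array's median. A pool of male and female islets argues for an intermediate Y-linked signal, but the higher of the 2 arrays numbered 03 reached 1.25% of the male level for Eif2s3y. For Kdm5d, a dimmer Y-linked transcript also chosen after its values were seen, the higher of the 2 reached 14.3% of the male level, with 6.18% for the female arrays. Xist on the arrays numbered 03 differed by 0.26 on the log2 scale from the arrays recorded as female, which is consistent with female animals whose sex was recorded wrongly in both genotypes; an exchange with female samples from outside the series stays open. The mean of the HIF glycolysis list was 1.18 on knockout 03 and -0.24 on control 03, which goes with their genotype labels. That list is itself a result of the genotype comparison, so it is no independent check of these labels. The brighter Vhl probe set had 467 on knockout 03 and 839 on control 03. It is a weak check, as control 01 had 457. No biological explanation was tested.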

How the results depend on the processing

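The alternatives without both arrays numbered 03, with the acinar marker mean and with the actin 3' to 5' ratio as a covariate were chosen after seeing the data. The 2 HIF lists kept their direction and passed under every alternative run, with means from 1.14 to 1.48 for glycolysis and 0.79 to 1.07 for the other HIF genes. Vhl stayed below control and short of the threshold under every alternative, at -0.92 to -0.48 when each array was left out in turn and -0.79 to -0.49 otherwise. No scaling moved the median of all tested genes by more than 0.1 on the log2 scale.

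The count of 2 genes became 5 at an adjusted p under 0.10, 4 with a pseudocount, 4 probe sets with every probe set on its own (0 of them without a single symbol), 4 with the robust variance model and 6 with the replicate block, where both genes of the main result passed. It ranged from 0 to 5 when each array was left out in turn. It was 0 without both arrays numbered 03 (268 genes at an unadjusted limma p under 0.05), with fewer samples in that fit and log2 differences of 5.85 for Ak4 and 3.11 for Prelid2. The mean of a gene's probe sets shared 0 genes with the main result, since dim probe sets enter that mean; for the other changes the cause was not tested. The replicate block changed no call among the lists except that the cell cycle passed (adjusted p 0.0195), and no call over all genes except that Ldha, Pgk1, Pfkl and Tpi1 were added.

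The 12 passing lists became 2 with an estimated correlation and 2 with fry, and ranged from 7 to 15 when each array was left out in turn. The beta-cell identity list, at -0.20, no longer passed with an estimated correlation (-0.20, adjusted p 0.220), fry (-0.20, adjusted p 0.307), without both arrays numbered 03 (-0.18, adjusted p 0.206) or with the acinar covariate (-0.18, adjusted p 0.0721); its mean ranged from -0.29 to -0.13 when each array was left out in turn.

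Several directions turned. Leaving out each array in turn gave -0.29 to 0.032 for Arnt, -2.38 to 0.83 for Cela3b, -0.063 to 0.34 for Gcg and -2.44 to 0.89 for Rnase1. The same step gave list means of -2.23 to 1.03 for acinar markers, -0.030 to 0.23 for lipid metabolism, -0.13 to 0.021 for mitochondrial biogenesis, -0.024 to 0.12 for oxidative phosphorylation, -0.21 to -0.025 for secretion and 0.022 to 0.14 for the unfolded protein response; where the mean kept its sign, camera's direction relative to other genes turned. Without both arrays numbered 03 the values were 0.32 for Cela3b, 0.086 for Rnase1, 0.18 for acinar markers, 0.026 for lipid metabolism, 0.012 for mitochondrial biogenesis, 0.038 for secretion and 9.3e-05 for the unfolded protein response. With the mean of a gene's probe sets they were 0.032 for Hif1a, 0.00047 for oxidative stress defence and 0.011 for the unfolded protein response. Quantile normalization gave -0.011 for Gcg, the stricter filter -0.013 for angiogenic factors, with fewer genes tested, and every probe set on its own -0.0040 for the unfolded protein response and -0.019 for oxidative stress defence. The cause of these turns was not tested beyond the samples or genes left out. Of the named genes, 723 of 742 values under alternatives other than leaving out an array, and 287 of 300 when an array was left out, kept their direction and side of the threshold. These shares say little about robustness, since only Ak4 and Prelid2 had a call to lose. Ak4 lost its call under 4 alternatives and Prelid2 under 5.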

Other observations

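The tests of Vegfa and of the marker lists in this part were chosen after the result was seen, as were the genes named in the next paragraph; the splits of the samples were planned beforehand.

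Beyond the fixed lists, several of the genes of lowest p were higher in knockout islets without passing the threshold over all genes. Among the 25 genes of lowest p, 24 were higher in the knockout and 11 belonged to the HIF lists, where 0.0883 would be expected by chance (hypergeometric p 1.1e-21 across genes, which are not independent replicates). Of the 13 genes in no list, 12 were higher. Mgarp, a mitochondrial protein, was 30.5-fold higher with a log2 difference of 4.93 (SE 0.87, adjusted p 0.282), Igfbp1, a binding protein for insulin-like growth factors, was 36.1-fold higher with 5.17 (SE 1.08, adjusted p 0.534), and Fam162a was 2.91-fold higher with 1.54 (SE 0.26, adjusted p 0.282). Mgarp passed with a pseudocount. Mif, a cytokine gene, was 3.58-fold higher (adjusted p 0.835), Tnfsf9, a costimulatory ligand, 4.31-fold (adjusted p 0.371) and Pdxp, a pyridoxal phosphatase, 7.66-fold (adjusted p 0.282). Control signals of Mgarp, Igfbp1, Pdxp and Tnfsf9 were at most 103, 49.7, 68.3 and 125, near or below the array medians, so their folds rest on dim values. All knockout signals of these 6 genes lay above all control signals.

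With 3 arrays in each group there are 10 splits of the samples, too few for a share under 0.05. The real split gave 2 genes, the highest other split gave 2, and 2 of the 10 splits gave as many. For lists the real split gave 12 and the highest other split 8, so 1 of the 10, the real one, gave as many. By the rule above the numbers pair the samples, though weakly for number 01. Of the 4 splits that part all 3 pairs the other 3 gave at most 0 genes and 8 lists. The mean change of the HIF glycolysis list was 1.37 in size in the real split and at most 0.70 in the others. Every knockout mean of this list lay above every control mean, so the real split had to give the largest value. The other splits keep part of the genotype difference, and the list passed in several of them (lowest adjusted camera p 3.2e-04). These values thus do not test whether the rise goes with genotype. A split of control 01, control 02 and knockout 02 against the rest gave 1 gene past the threshold and 2086 genes at an unadjusted p under 0.05, against 300 in the real split, which points to a structure of the samples. It sets the arrays with actin 3' to 5' ratios of 3.83, 3.34 and 3.43 against those with 15.1, 11.3 and 7.97. The Gapdh ratios did not part this way, at 5.71, 4.78 and 6.12 against 5.74, 11.9 and 4.64. Acinar means nearly did, at 0.63, 1.06 and 1.42 against -1.69, 0.64 and -5.10. What the structure stands for was not tested. With the actin ratio as a covariate, the real comparison gave 2 genes, Ak4 and Prelid2, and 12 lists, 11 of them shared. Acinar markers were lost (-0.73, adjusted p 0.0557) and duct markers gained (0.44, adjusted p 0.0364).

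Vegfa was not higher in the knockout while the HIF lists rose as groups, though 18 of the 24 other HIF genes did not pass when adjusted over the list alone. A rise of the size of that list's mean, 0.97, was excluded on both bright Vegfa probe sets, with upper 95% bounds of 0.14 on the chosen and 0.84 on the second, which differed by -0.37. The list's median was 0.61, so a rise of that size is excluded on the chosen probe set and not on the second. The list's mean went down to 0.79 under the alternatives, a rise that the second probe set does not exclude either. The bound of the second probe set was not refitted with arrays left out. With each array left out in turn the upper bound on the chosen probe set went from 0.06 without knockout 03 to 0.38 without control 01, with 0.31 without knockout 01, 0.30 without control 02 and 0.23 without knockout 02. The choice of probe set and the spread between arrays are thus argued against for a rise of 0.97. Saturation of the chosen probe set is not decided by its own change of -0.46 (SE 0.27), under 2 standard errors below control. The second probe set had a geometric mean signal of 222 against 3477 for the chosen one, and it too excluded a rise of 0.97. At this dimmer signal, that argues against saturation as what hid a rise of 0.97, while a hidden rise of 0.61 or 0.79 stays open. Whether the genotype acts on Vegfa in beta cells stays open and untested, since whole islets were measured.

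Markers of several kinds of cells other than beta cells were higher in the knockout arrays, but acinar markers had a mean log2 difference of -1.01. The test of 6 lists was chosen after the result was seen and leaves out the acinar list. Duct and leukocyte markers, which it includes, did not pass on their own. The mean of 6 lists (other endocrine, duct, endothelial, matrix, leukocyte and neural) differed by 0.40, 0.31 and 0.86 in the pairs numbered 01, 02 and 03, and all 6 lists were above 0 in every pair. Whether the pattern rests on knockout 03 is not decided: without the pair numbered 03 the 6 lists differed by 0.35 and the matrix list by 0.65, neither above 2 control SDs, with control SDs of 0.21 and 0.50. A first version that left out knockout 03 and kept control 03 gave 0.44 for the 6 lists and 0.56 for the matrix list. For the 6 lists this was above 2 control SDs, which were 0.42, so the versions differ there. For the matrix list it was not above 2 control SDs. A lower share of beta cells could raise all 6 lists alike; the matrix list exceeded the mean of the other 5 by 0.60 (SE 0.36), which decides neither way, and a first version of the same test against the other endocrine markers gave 0.74 (SE 0.42).

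Exocrine tissue carried over with the knockout islets, as the whole cause of the higher 6 lists, is argued against in the pair numbered 03 and less firmly in that numbered 01. Each of these rests on 1 knockout array. In the pair numbered 01 some acinar markers were bright, such as Cela3b at 31939 in control and 40510 in knockout, with array maxima of 55556 and 75380. A rise could be compressed at such signals, which was not tested. The dimmer Prss3, at 1734 and 1002, was not higher in that knockout. Acinar markers differed by 0.01, 0.35 and -3.41 in the pairs numbered 01 to 03, where the 6 lists differed by 0.40, 0.31 and 0.86. They were thus lower where the 6 lists were highest. A first version of this test counted the pairs in which they exceeded the 6 lists, found 1 of 3 and decided neither way. Over the 6 arrays the part of the 6-list difference of 0.52 that goes with the acinar mean was 0.02, with an upper 95% bound of 0.15. That bound does not decide the question, since it leans on knockout 03, whose acinar mean was -5.10 relative to controls. With the acinar mean as a covariate the difference was 0.51 (SE 0.19), but its 95% interval, from -0.09 to 1.10, included 0 because 3 degrees of freedom remained. For the pair numbered 02 alone carry-over stays open, as acinar markers there exceeded the 6 lists by 0.048, less than the control SD of 0.21. A change of vessels and stroma with genotype stays open and untested.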
